A study of Mus musculus with 23 samples.

How the data were processed

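RNA was sequenced from 23 libraries in 7 groups. All are of distal forelimbs of mouse embryos at stage E11.5 except 3 Inv1 libraries of embryonic stem cells, which enter no comparison here. Per the labels, RNA was extracted with RNeasy columns and libraries followed a standard Illumina preparation. The submitters' processing notes name STAR, DESeq2 and the mouse build mm9, without versions. Nothing in the labels states that replicate libraries came from different litters, so the p-values measure the spread between these libraries.

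The files are 5 tables of the authors' own comparisons. Each gives, per the file headers, a mean normalised count over libraries, which is a signal pooled over all libraries of the authors' fit, a log2 fold change with its standard error on the log2 scale, a Wald score, and the deposited p-value and adjusted p-value. In every row the Wald score equals the log2 fold change over its SE. The 4 tables against wild type give identical means for a gene, so the authors made them from 1 fit of 18 libraries, and they list 78, 74, 79 and 72 genes for Inv1 to Inv4. Their adjusted p-values were made over the whole genome, since the smallest in Inv1 implies 17996 tests. In Inv2 and Inv4 the same ratio is 731 and 4160, because genes outside the lists had smaller p-values there. By the same construction, in a step chosen after seeing the data, p over adjusted p of a called gene is a lower limit of the share of all tested genes called, and that of a gene not called an upper limit. SE values in those tables are at most 0.269 even for genes with a mean under 10, as in a fit with fold changes shrunk toward 0, so their fold changes are conservative for low genes. The table of Inv1DelCTCF against Inv1 comes from a separate fit of 5 libraries, lists 34682 genes with no shrinkage visible (SE up to 4.56), and its means add up to 3.02e+07 normalised counts. Fold changes were therefore tested within each table, and mean counts were set across tables only to find the sign of the fold changes, as described below, and for the residual of Wnt6. An adjusted p that the authors left empty stays empty here.

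The headers do not say which group is the numerator. The group means of 49 genes with a mean of at least 300 were rebuilt from the joint fit and set against the means of the other table under each of the 4 possible sign conventions. The median absolute residual was 0.0124 on the log2 scale when positive values mean higher in the mutant in the wild type tables and higher in Inv1 in the other table. Under the other conventions it was 0.107, 0.117 and 0.132. The limit of 300 was 1 of 3 tried, and with a mean of at least 100 the residual was 0.0165 against 0.114 or more, and with at least 20 it was 0.0199 against 0.124 or more. Ptprn, with a mean of 81.2, lies outside the set of 49, and taken alone its residual was 0.373 under the convention used and -0.239 with the sign of the Inv1DelCTCF table reversed, so that gene by itself lies closer to the reversed sign. This first convention is used throughout, and the sign of the Inv1DelCTCF table was turned so that positive is higher in Inv1DelCTCF.

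A gene was called at a deposited adjusted p under 0.05. Differences between inversions were tested as the difference of log2 changes over the root of the summed squared SE, with a normal p and Benjamini-Hochberg adjustment over the genes of each pair. Shared wild type libraries make that test conservative. Correlations across genes were tested by 100000 permutations, beside 1000 simulations of unchanged groups sharing control libraries. The 20 gene lists were fixed before the data were examined, and each list's median log2 change was set against 10000 random lists matched on mean count in 10 bins, two-sided, with Benjamini-Hochberg adjustment over lists. This test treats genes as independent, and no correlation between genes could be estimated without values per library. Locus genes were compared with other genes by Fisher's exact test.

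Named genes followed a rule fixed before the data were examined. It takes every called gene of the 3 locus lists, 5 genes whatever their p (Epha4, Pax3, Wnt6, Ihh and Resp18), the 10 highest and 10 lowest called log2 changes with a mean of at least 10, and up to 4 genes of each list with the smallest adjusted p. Dnajb2 and Fam134a in Inv1DelCTCF fall outside it and were named because they had risen in Inv1. Of the genes it takes, 1 is not reported here.

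The reference at hand is GRCm38, not the authors' build, so no coordinates are printed and it served only for gene names, gene order and transcript sequence. All 79 genes of the wild type tables matched it. GC content and length came from the longest GENCODE transcript of a gene and were found for 97.6% of the genes with an adjusted p and for 97.3% of the called genes. The trend subtracted had terms up to the cube in GC content and in log2 length and their product, fitted by weighted least squares.

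Steps across many genes were tested on simulated data. In 100 simulated tables of Inv1DelCTCF against Inv1 with 11218 genes, 97.8% of 200 genes changed by 1 on the log2 scale were recovered, with a mean of 5.05% of calls false and at most 8.72% in a table. With a planted trend, false calls fell from a mean of 604.3 to 10.5 after its subtraction. That trend was a straight line in a random property, unrelated to the changed genes, and the same property was used in the fit. The run therefore does not test a trend in a property tied to true changes. For the difference of Inv3 and Inv1 over 78 genes, 87.9% of genes differing by 1 were recovered. The direction check recovered the sign in 100% of simulated tables over 72 genes. There the Inv1 level was known and not rebuilt from shrunken fold changes, so the rebuilding step was not tested. Of lists of unchanged genes, 3% had a permutation p under 0.05 over 21940 genes.

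Alternatives covered other thresholds, minimum changes and counts, adjustment over the rows of each table, Wald scores in place of log2 changes, other bins and the removal of the shared wild type part. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.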

Results

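RNA was sequenced from distal forelimbs dissected from mouse embryos at stage E11.5. The libraries came from 5 wild type samples, from mutants carrying 1 of 4 engineered inversions, and from a mutant that by its name combines the first inversion with a deletion of a CTCF binding site. The inversions move an enhancer cluster out of the domain of the limb gene Epha4 and into a neighbouring gene-dense part of chromosome 1, so each comparison asks which genes around the new position change their expression. There were 3 libraries of Inv1, 4 of Inv2, 3 of Inv3, 3 of Inv4 and 2 of Inv1DelCTCF, and a further 3 Inv1 libraries from embryonic stem cells were not analysed here. The values are the authors' comparisons between groups, without a value per library, so the depth of each library is unknown and the spread between libraries is known only through the authors' standard errors (SE). The 4 tables against wild type list 79 genes between them, all on chromosome 1 in the GRCm38 annotation, and 72 of these are in all 4. The table of Inv1DelCTCF against Inv1 lists 34682 genes, of which 11218 have an adjusted p.

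In Inv1, a block of neighbouring genes rose. Ptprn, which encodes a protein of dense-core vesicles, was 14.1-fold higher than in wild type in the authors' deposited table, with a 95% interval of 10.2 to 19.7 from its SE. Tuba4a, an alpha-tubulin gene, was 3.58-fold higher (3.12 to 4.10), and Resp18, a neuroendocrine gene of low abundance, was 3.15-fold higher (log2 change 1.66, SE 0.212) in the authors' deposited table. The mean normalised count of Resp18 was only 4.81, so its shrunken fold change may understate the rise and is not a precise measure of it. Dnajb2, a co-chaperone gene, rose by a log2 change of 0.94 (SE 0.068, adjusted p = 1.21e-39) and Dnpep, an aminopeptidase gene, by 0.56 (SE 0.063, adjusted p = 1.74e-15) in the authors' deposited table. Tuba4a, Dnajb2, Ptprn, Resp18 and Dnpep follow one another without a gap among the listed genes.

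Epha4 itself, which encodes an ephrin receptor, fell in Inv1. Its log2 change in the authors' deposited table was -0.44 (SE 0.098, adjusted p = 0.00739), which is 0.736 of the wild type level. Fam134a was the sixth gene to rise, with a log2 change of 0.31 (SE 0.075, adjusted p = 0.0299) in the authors' deposited table. Wnt6, a ligand gene of the limb ectoderm, had a log2 change of 0.03 (SE 0.140), Ihh one of 0.13 (SE 0.267) and Pax3 one of -0.43 (SE 0.195, adjusted p = 0.663) in the authors' deposited table, and none of these passed the test. Of the 78 genes listed for Inv1, 6 rose, 1 fell and 17 had an unadjusted p under 0.05 in the authors' Wald test with genome-wide adjustment. Within the list of the gene-dense side, 6 of 29 genes rose and 10 did when adjusted over the list alone. All 29 of that list had a positive log2 change, with a median of 0.25, and across the 78 genes the log2 change had a Spearman correlation of 0.455 with the GC content of the transcript. Across the 3 locus lists together, 7 of 61 genes were called and 12 when adjusted over the list alone.

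In Inv2, Ihh rose and Pax3 fell. Ihh, which encodes the Indian hedgehog ligand, was 2.59-fold higher than in wild type (95% interval 1.80 to 3.71, adjusted p = 0.000185) in the authors' deposited table. Slc23a3, a membrane transporter gene close to Ihh with a mean normalised count of only 9.40, had a log2 change of 1.18 (SE 0.269, adjusted p = 0.00344) in the authors' deposited table. Pax3, a transcription factor gene of muscle precursors on the other side of Epha4, was at 0.538 of the wild type level (0.417 to 0.695, adjusted p = 0.00102) in the authors' deposited table. Those 3 genes were the only ones called among the 74 listed, and 16 had an unadjusted p under 0.05. Adjusted over the list alone, the 3 locus lists held the same number, 3 of 60. In the authors' deposited table the log2 change of Epha4 was -0.22 (SE 0.090, adjusted p = 0.204), that of Wnt6 was -0.08 (SE 0.131), and Resp18 was listed at 0. With a mean normalised count of 4.81, that value of Resp18 is no evidence of an unchanged level.

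In Inv3, Fev changed more than any other listed gene. Fev, an ETS transcription factor gene known from serotonergic neurons, was 108-fold higher than in wild type (95% interval 78.5 to 150, adjusted p = 2.57e-174) in the authors' deposited table. The Fev level rebuilt from the joint fit was only 5.92 in wild type and 641 in Inv3, so the size of its fold rests on a low count. Its neighbours Ihh, 3.40-fold higher (2.37 to 4.89), and Cdk5r2, with a log2 change of 1.43 (SE 0.250), also rose in the authors' deposited table. Pax3 was at 0.373 of the wild type level (0.284 to 0.490, adjusted p = 4.14e-10) in the authors' deposited table. Genes farther away rose too in the authors' deposited table, among them Abca12 by 1.32 (SE 0.257), Prkag3 by 1.28 (SE 0.257) and Kcne4 by 1.26 (SE 0.268) on the log2 scale. Des, the muscle intermediate filament gene, rose by 0.81 (SE 0.268, adjusted p = 0.0129) in the authors' deposited table.

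The remaining Inv3 changes were smaller. Tuba4a, raised in Inv1, fell here by 0.50 on the log2 scale (SE 0.108, adjusted p = 8.84e-05) in the authors' deposited table, and Sgpp2 fell by 0.49 (SE 0.169). Inha rose by 0.48, Igfbp5 by 0.38, Slc4a3 by 0.39, Tmbim1 by 0.37, Glb1l by 0.32 and Dnajb2 by 0.21 in the authors' deposited table. Farsb, Xrcc5, Arpc2, Rqcd1, Atic, Ttll4, Abcb6, Cul3, Dnpep and Aamp fell, with log2 changes between -0.29 (Ttll4) and -0.16 (Dnpep) in the authors' deposited table. Epha4 had a log2 change of -0.07 (SE 0.098) and Wnt6 one of -0.01 (SE 0.141) in the authors' deposited table. Resp18 was listed at 0, which again is no evidence of an unchanged level. Of the 79 genes listed for Inv3, 13 rose and 13 fell, which is 32.9% called. The ratio of deposited p to adjusted p places the share called among all genes the authors tested between 27.6% and 31.1%, so calls around the locus are set in a change across the genome. In the gene-dense list 8 of 29 rose and 3 fell, in the list centromeric of Wnt6 2 of 18 rose and 4 fell, and in the Epha4 to Pax3 list 1 of 14 rose and 4 fell. Adjusted over the list alone, the 3 lists together again held 22 called genes of 61.

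In Inv4, Prkag3 changed more than any other listed gene. Prkag3, which encodes a muscle subunit of AMP-activated kinase, was 8.08-fold higher than in wild type (95% interval 5.73 to 11.4, adjusted p = 3.57e-29) in the authors' deposited table. Its rebuilt level in wild type was also low, at 11.7. Cyp27a1, a sterol hydroxylase gene, was 2.92-fold higher (2.48 to 3.43, adjusted p = 6.45e-35) and Ihh 3.34-fold higher (2.32 to 4.80, adjusted p = 4.77e-08) in the authors' deposited table. Pax3 was at 0.558 of the wild type level (adjusted p = 0.000871), and Tuba4a fell by 0.44 on the log2 scale (SE 0.111) in the authors' deposited table. Abca12 rose by 1.13 (SE 0.259), Kcne4 by 0.91 (SE 0.268), Des by 0.73 (SE 0.268), Fam124b by 0.50 (SE 0.188), Igfbp5 by 0.47 (SE 0.150), Tmbim1 by 0.34 (SE 0.081) and Wdfy1 by 0.24 (SE 0.074) in the authors' deposited table. Abcb6, Rpl37a and Dnpep fell, with log2 changes of -0.30, -0.25 and -0.18 in the authors' deposited table. Epha4 had a log2 change of -0.15 (SE 0.098, adjusted p = 0.266) and Wnt6 one of 0.04 (SE 0.142) in the authors' deposited table. Of the 72 genes listed for Inv4, 10 rose and 5 fell, which is 20.8% called. The share among all genes tested lies between 19.8% and 23.4% in the same way, limits that hold the 20.8%, and the difference was not tested. In Inv1 that share lies between 0.133% and 0.295%, against 8.97% of the listed genes, and in Inv2 between 0.313% and 5.22%, against 4.05%. The 3 locus lists held 11 called genes of 58, and the same number when adjusted over the list alone.

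**Figure D1:**
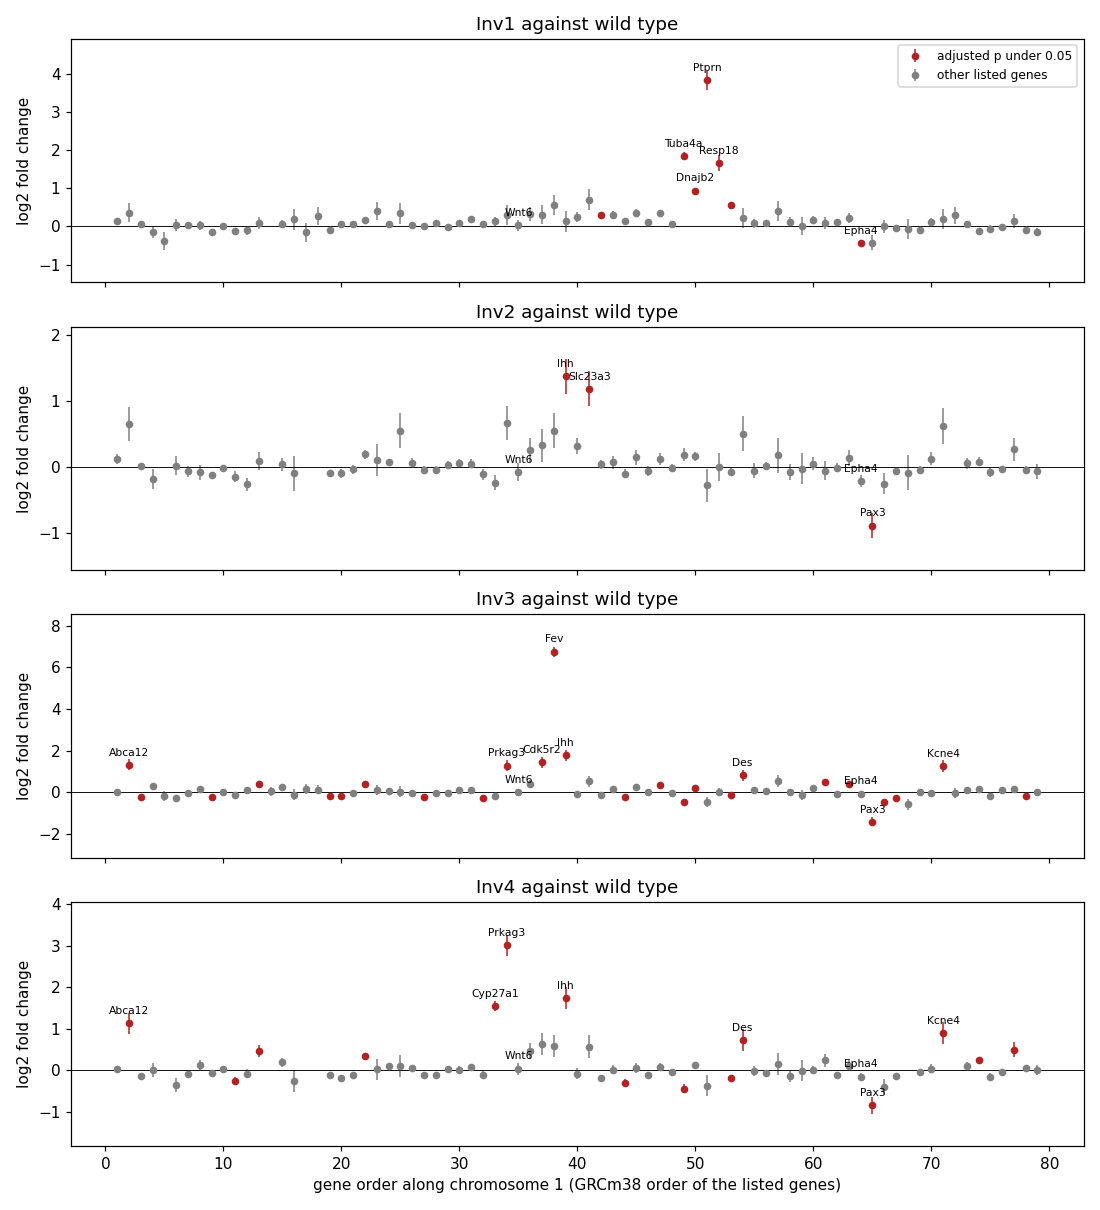
Log2 fold change against wild type (y axis, error bars 1 SE) of each listed gene, placed by its rank in gene order along chromosome 1 (x axis), for each of the 4 inversions; red points have an adjusted p under 0.05. The raised genes of Inv1 sit together around Ptprn (3.82), whereas Fev (6.76) stands out in Inv3 and Prkag3 (3.01) in Inv4.

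Set against each other, the inversions differed in their effect on single genes. For Ptprn the difference from Inv1 was -4.10 in Inv2, -4.30 in Inv3 and -4.19 in Inv4 on the log2 scale, tested on the values of the authors' deposited table, with adjusted p values of 2.40e-30, 8.33e-33 and 9.01e-31. By the same test Fev was higher in Inv3 than in Inv4 (the difference of Inv4 minus Inv3 was -6.17, SE 0.357), and Cyp27a1 was higher in Inv4 than in Inv3 by 1.72 (SE 0.171). Prkag3 was higher in Inv4 than in Inv3 by 1.74 (SE 0.361, adjusted p = 3.47e-05). Ihh was higher than in Inv1 by 1.24 (SE 0.377) in Inv2, by 1.64 (SE 0.378) in Inv3 and by 1.61 (SE 0.378) in Inv4. Pax3 was lower than in Inv1 in Inv3, with a difference of -0.997 (SE 0.280, adjusted p = 0.00322), while the differences of -0.47 (SE 0.271) for Inv2 and -0.41 (SE 0.280) for Inv4 did not pass.

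Of the 79 genes, 35 were called in at least 1 inversion, 23 of them in exactly 1 and none in all 4. Ihh was the 1 gene called higher in 3 inversions and Pax3 the 1 gene called lower in 3. Tuba4a and Dnpep were the 2 genes called in both directions, higher in Inv1 and lower in Inv3 and Inv4. Inv3 and Inv4 shared 7 called rises and 4 called falls, where independent calls would give 1.81 and 0.903. Inv1 and Inv4 shared none, where independent calls would give only 0.694 and 0.0694. These counts were not tested, since the comparisons share the wild type libraries.

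Across genes, the Spearman correlation was highest for Inv3 and Inv4, at 0.828 over 72 genes (permutation p = 1e-05, the smallest the 100000 permutations can give, adjusted p = 1.75e-05). The 4 comparisons share the wild type libraries, and unchanged groups simulated against shared controls gave a mean Spearman correlation of 0.344 for that pair, with a 95% range of 0.0820 to 0.565. The Pearson correlation of Inv3 and Inv4 was 0.483, inside the range of 0.0465 to 0.637 of unchanged groups, although its permutation test against 0 passed (adjusted p = 0.0233). It was higher for Inv2 and Inv4 (0.667, against 0.104 to 0.652 in unchanged groups, but 0.489 on Wald scores, inside 0.217 to 0.592) and for Inv2 and Inv3 (0.557, against 0.0807 to 0.644). The covariance of Inv3 and Inv4 was 0.235 against a simulated 0.00844, that of Inv2 and Inv3 was 0.156 against 0.00913, and that of Inv2 and Inv4 was 0.111 against 0.00884. For Inv1 it was 0.0224 with Inv2 (upper simulated limit 0.0184) and 0.0313 with Inv3 (upper limit 0.0188). With Inv4 it was -0.00175, against a simulated mean of 0.00832 and below the lower limit of 0.000746. The covariance with Inv2 lost its excess with a mean count of at least 10 (0.0153, limit 0.0161) but kept it on Wald scores (1.68, limit 0.671). The covariance with Inv3 kept its excess with a mean count of at least 10 (0.0311, limit 0.0155) but lost it on Wald scores (0.290, range 0.154 to 0.624). That with Inv4 stayed below its range on Wald scores (-0.776, lower limit 0.147). The Spearman correlation of Inv1 and Inv2, 0.627, lay above the simulated limit of 0.586, but not on Wald scores (0.542, limit 0.578), while those of Inv1 with Inv3 (0.395) and Inv4 (0.339) lay within their ranges. The Pearson correlations of Inv1 with Inv3 (0.0659, lower limit 0.0930) and Inv4 (-0.00628, lower limit 0.0389) lay below their ranges. With a mean count of at least 10 that of Inv3 lay within it (0.0626, lower limit 0.0312). The changes of Inv1 against wild type and of Inv1DelCTCF against Inv1 had a Pearson correlation of -0.348 and a Spearman correlation of -0.277, inside the ranges that shared Inv1 libraries alone gave (-0.669 to -0.101 and -0.646 to -0.197). Their covariance of -0.0777 lay just below the simulated lower limit of -0.0752, and farther below it with a mean count of at least 10 (-0.0776, limit -0.0376) and on Wald scores (-2.95, limit -0.752). Genes are not independent replicates, these were 7 correlations of 1 family, and part of any excess may come from the shared controls, which could not be split without values per library.

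The deletion in Inv1DelCTCF asks whether the genes raised in Inv1 depend on the CTCF site. Ptprn, Tuba4a and Dnpep fell relative to Inv1. With the sign turned so that negative is lower in Inv1DelCTCF, the log2 changes in the authors' deposited table were -0.80 for Ptprn (SE 0.196, adjusted p = 0.00174), -0.61 for Tuba4a (SE 0.106, adjusted p = 2.60e-06) and -0.32 for Dnpep (SE 0.080, adjusted p = 0.00222). Dnajb2 at -0.15 (SE 0.081, adjusted p = 0.226) and Fam134a at -0.19 (SE 0.092, adjusted p = 0.165) did not pass, and Resp18 at -0.69 (SE 0.544) had no adjusted p in the authors' deposited table. All 6 genes raised in Inv1 thus had a negative sign. Each fall was smaller than the rise in Inv1, and Inv1DelCTCF was not compared with wild type. Epha4 had a log2 change of -0.03 (SE 0.055), Pax3 one of -0.08 (SE 0.225), Wnt6 one of -0.43 (SE 0.155, adjusted p = 0.0509) and Ihh one of 0.89 (SE 0.671, no adjusted p) in the authors' deposited table.

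**Figure D2:**
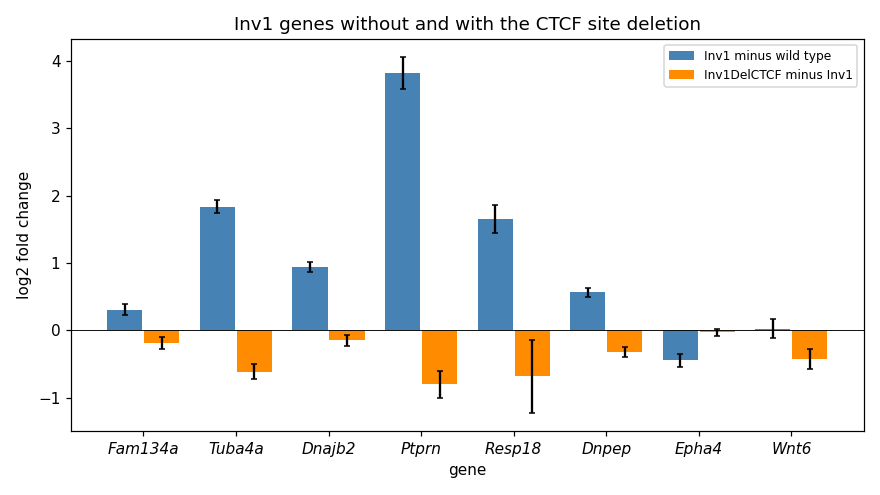
Log2 fold change (y axis, error bars 1 SE) of the 6 genes raised in Inv1, of Epha4 and of Wnt6 (x axis), for Inv1 against wild type (blue) and for Inv1DelCTCF against Inv1 (orange). Ptprn has 3.82 in the first comparison and -0.80 in the second, and the first comparison's fold changes were shrunk toward 0 by the authors' fit.

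Genes near the locus were not called more often than others in Inv1DelCTCF. In the authors' deposited table, 5 of 45 locus genes with an adjusted p were called, against 1307 of 11173 other genes (odds ratio 0.944, Fisher's exact test, two-sided p = 1). The gene-dense list as a whole had a median of -0.13 over 30 genes (permutation p = 0.0102, adjusted p = 0.0331), and one of 0.01 (adjusted p = 0.857) after the GC trend described below was subtracted. It did not pass with a mean count of at least 10 either (adjusted permutation p = 0.0923). Besides the genes above, the called locus genes were Ttll4 at -0.28 (SE 0.090) and Tns1 at -0.23 (SE 0.075) in the authors' deposited table. Adjusted over the list alone, 5 locus genes were called again. Over all genes, 427 were higher and 885 lower in Inv1DelCTCF, 1312 in all, and 4 of them had an absolute log2 change of at least 1. The median absolute log2 change of the called genes was 0.306.

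Those genome-wide changes followed GC content. Across 10945 genes the log2 change had a Spearman correlation of -0.517 with the GC content of the longest transcript and of 0.0813 with its length. The median GC content was 55.6% among the genes called lower and 43.6% among those called higher. When a trend in GC content and length was subtracted, an alternative chosen after seeing the data, 395 genes were called in place of 1275 among genes with a known sequence, and 309 were in both sets. Of the genes above, Tuba4a (-0.55, adjusted p = 7.88e-05) and Ptprn (-0.62, adjusted p = 0.0468) passed after the subtraction, whereas Dnpep went from -0.32 to -0.23 with the same SE of 0.080 and did not (adjusted p = 0.0760). Tns1 went from -0.23 to -0.06 (adjusted p = 0.750) and Ttll4 from -0.28 to -0.25 (adjusted p = 0.0877), and neither passed. Of 56 called genes with a known sequence picked by the rule for naming genes, 25 passed after the subtraction. The subtraction leaves every SE as it was, so a call ended because the log2 change came closer to 0 or because the adjustment over fewer small p-values was stricter.

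Genes of fibroblast growth factor signalling and the apical ridge, the signalling rim of the limb bud, were lower in Inv1DelCTCF. In the authors' deposited table, 7 of 15 fell and none rose, among them Etv4 at -0.61 (SE 0.112), Spry1 at -0.55 (SE 0.139), Etv5 at -0.48 (SE 0.097) and Cyp26b1 at -0.42 (SE 0.107). The list had a median of -0.42 over 19 genes, below all of 10000 random lists matched on mean count (permutation p = 0.0002, the smallest they can give, adjusted p = 0.00133). After the GC trend was subtracted the median was -0.37 (adjusted p = 0.0010), Etv4 and Etv5 passed, and Spry1 at -0.41 (adjusted p = 0.0675) and Cyp26b1 at -0.28 (adjusted p = 0.123), with their SE unchanged, did not. Adjusted over the list alone, 8 genes of this list were called, all lower.

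The ectoderm, Wnt and limb patterning lists were lower as well. Among ectoderm genes 5 of 14 fell in the authors' deposited table, including Cldn6 (-0.53), Krt18 (-0.56), Cdh1 (-0.39) and Krt5 (-0.30), and the list median was -0.21 (adjusted permutation p = 0.00320). Among Wnt target genes 5 of 15 fell, including Tcf7 (-0.51), Lef1 (-0.30), Znrf3 (-0.30) and Axin2 (-0.25) in the authors' deposited table. The list median was -0.15 (adjusted permutation p = 0.0350, but 0.0630 over only the genes with an adjusted p). Among limb patterning factors 7 of 29 fell and 1 rose, including falls of Sall4 (-0.85), Lmx1b (-0.44), Lhx2 (-0.41) and Tbx2 (-0.33) in the authors' deposited table, with a list median of -0.16 (adjusted permutation p = 0.0020). After the GC trend was subtracted the ectoderm list was at -0.17 (adjusted permutation p = 0.0010), the Wnt list at -0.11 (0.0264) and the patterning list at -0.08 (0.0565). Among the named genes Cldn6, Cdh1, Tcf7, Lef1 and Sall4 then passed. Krt18 at -0.43 (SE 0.165, adjusted p = 0.125), Krt5 at -0.16 (SE 0.076, 0.234), Znrf3 at -0.25 (SE 0.088, 0.0928) and Axin2 at -0.14 (SE 0.069, 0.266) did not, nor did Lmx1b at -0.28 (SE 0.119, 0.196), Lhx2 at -0.24 (SE 0.110, 0.236) and Tbx2 at -0.08 (SE 0.089, 0.698). Adjusted over the list alone, 7 ectoderm, 6 Wnt target and 13 patterning genes were called, of which 1, 1 and 2 were higher.

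Cartilage and muscle genes lay on the other side. The cartilage list had a median of 0.45 over 19 genes and the muscle list one of 0.59 over 20 (both with permutation p = 0.0002, the smallest the random lists can give, adjusted p = 0.00133). Single genes varied widely, so that only Col11a1 of 17 cartilage genes rose (0.44, SE 0.127) and none of 17 muscle genes did in the authors' deposited table, and the same counts held when adjusted over the list alone. The values of Acan (1.56, SE 0.683), Matn4 (1.12, SE 0.498), Myh3 (1.11, SE 0.612), Tnnc1 (1.06, SE 0.604) and Chrng (0.87, SE 0.472) in the authors' deposited table did not pass. In a comparison chosen after seeing the data, the median SE was 0.246 in the cartilage list and 0.466 in the muscle list, where matched random lists had 0.0972 and 0.148. The spread between libraries of 1 group was thus larger for these genes than for others of like abundance. Random lists matched on mean count alone therefore understate the spread of the cartilage and muscle medians. Smaller excesses of SE were found in lists that were lower, at 0.143 against 0.105 for the FGF list, 0.110 against 0.0886 for the Wnt list and 0.0981 against 0.0850 for the patterning list. After the GC trend was subtracted the medians were 0.57 and 0.69 (adjusted permutation p = 0.0010 for each).

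**Figure D3:**
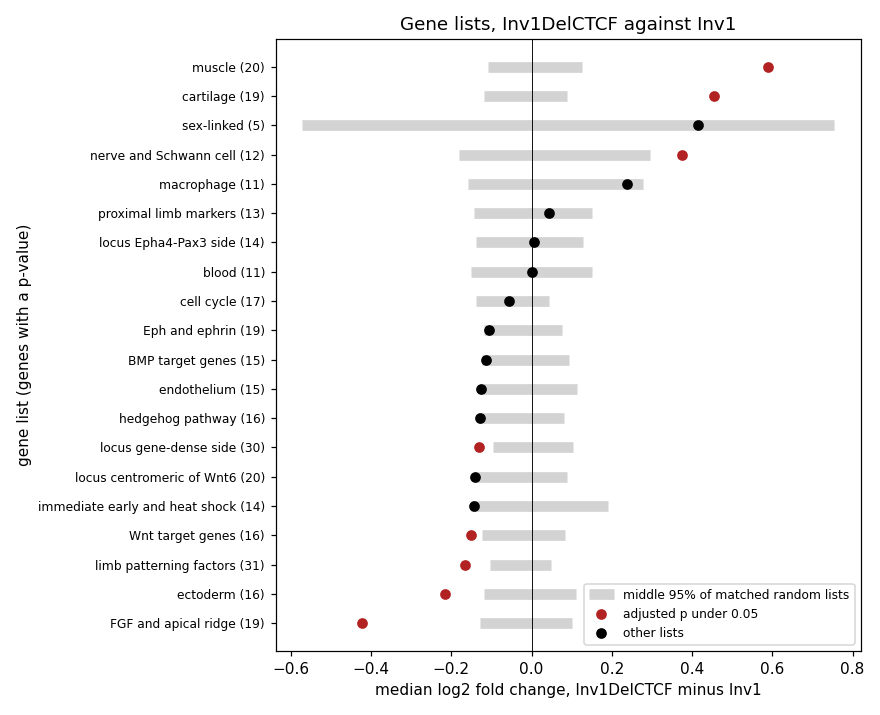
Median log2 fold change of each gene list in Inv1DelCTCF relative to Inv1 (x axis), with the number of its genes that have a p-value in brackets (y axis); grey bars span the middle 95% of random lists matched on mean count and red points have an adjusted p under 0.05. The FGF and apical ridge list is the lowest at -0.42 and the muscle list the highest at 0.59.

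The remaining lists were tested in the same way. The Eph and ephrin (adjusted permutation p = 0.123), BMP target (0.123), cell cycle (0.837), blood (0.984) and endothelial (0.0908) lists did not pass as a whole. In the authors' deposited table, 3 of 13 hedgehog genes fell, including Ptch1 (-0.33) and Smo (-0.21), with a list median of -0.13 (adjusted permutation p = 0.0987). Of 18 Eph and ephrin genes 5 fell, including Epha2 (-0.59), Ephb2 (-0.35), Efna2 (-0.33) and Ephb4 (-0.32), and of 15 BMP target genes 4 fell, including Bmp4 (-0.44) and Id1 (-0.38), and Nog rose (0.94) in the authors' deposited table. Of 17 cell cycle genes 4 fell, namely Mcm2 (-0.29), Mcm5 (-0.25), Plk1 (-0.23) and Mcm3 (-0.21), in the authors' deposited table. The embryonic globin genes Hba-x (-0.44) and Hbb-bh1 (-0.28) fell among 9 blood genes, and Cdh5 (-0.24) among 14 endothelial genes, in the authors' deposited table. Of the proximal limb markers Shox2 rose (0.27, adjusted p = 0.0487) in the authors' deposited table, 1 of 9, and not when adjusted over the list alone. No gene of the macrophage, nerve, immediate early or sex-linked lists passed, and the nerve list had a median of 0.38 (adjusted permutation p = 0.0331). The nerve list did not pass after the GC trend was subtracted (0.35, adjusted p = 0.0565), with a mean count of at least 10 (0.0923) or among genes with an adjusted p (0.147), whereas the macrophage list (0.38, adjusted p = 0.0293) and its gene Csf1r (0.52, adjusted p = 0.0430) passed after the trend was subtracted. Of the called genes named in this paragraph, only Hba-x, Hbb-bh1 and Nog passed after the subtraction. Epha2 was then at -0.45 (SE 0.176, adjusted p = 0.142), Ephb2 at -0.19 (SE 0.095, 0.293), Efna2 at -0.16 (SE 0.098, 0.418), Ephb4 at -0.15 (SE 0.063, 0.182), Bmp4 at -0.38 (SE 0.131, 0.0750) and Id1 at -0.28 (SE 0.111, 0.137). Mcm2 was at -0.24 (SE 0.085, 0.0877), Mcm5 at -0.20 (SE 0.078, 0.149), Plk1 at -0.11 (SE 0.082, 0.563), Mcm3 at -0.15 (SE 0.072, 0.276), Ptch1 at -0.29 (SE 0.095, 0.0632), Smo at -0.05 (SE 0.063, 0.747), Cdh5 at -0.18 (SE 0.079, 0.201) and Shox2 at 0.28 (SE 0.097, 0.0734). Adjusted over the list alone, 8 hedgehog, 6 Eph and ephrin, 8 BMP target, 4 cell cycle, 3 blood and 1 endothelial gene were called. Of these, 2 hedgehog, 2 BMP target and 1 blood gene were higher.

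Among single genes, Trim71, a stem cell factor, had the lowest log2 change of the called genes with a mean count of at least 10, at -1.04 (SE 0.207, adjusted p = 7.80e-05) in the authors' deposited table. Bhlha9, Ier5l, Padi3, H1fx, Mif, Sall4, Ptprn, Mogat2 and AK145489_gene completed the 10 lowest, between -0.98 and -0.79 in the authors' deposited table. Mybpc1, a myosin-binding protein gene, was the highest at 1.26 (SE 0.194, adjusted p = 4.11e-08), followed by AF357425_gene (1.14) and Egfl6 (1.08) in the authors' deposited table. Hmg1l1, Gria2, Nog, Rxrg, Far2, Rpl14-ps1 and Cdh29 completed the 10 highest, between 0.96 and 0.82 in the authors' deposited table. Rpl14-ps1 and Hmg1l1 have near-identical relatives elsewhere in the genome, so their values are uncertain. Trim71 (-0.92), Mybpc1 (1.25) and Egfl6 (1.04) passed after the GC trend was subtracted, while H1fx went from -0.96 to -0.61 with an SE of 0.330 and did not (adjusted p = 0.336), nor did Ier5l (-0.72, SE 0.287, 0.150) and Rxrg (1.02, SE 0.332, 0.0567).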

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

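Tests chosen only after the result was seen are those of Ihh, Pax3 and Des, the 2 of a different share of ectoderm cells, those of the cartilage, muscle and FGF lists and of the genes raised in Inv1 after the trend was subtracted, and the straight line in GC content. The tests of the number of called genes after the GC trend, of the let-7 list and of the genes raised in Inv1 as deposited were fixed before their results were seen.

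The effects of 2 inversions differed for 20 genes by the test of the difference itself, in 43 of 442 differences tested over 6 pairs. Values are differences of log2 changes against wild type, and those of Resp18 rest on listed values of 0 in Inv2 and Inv3. In Inv2 minus Inv1 they were -4.10 for Ptprn, -1.66 for Tuba4a, -1.66 for Resp18, -0.78 for Dnajb2, -0.64 for Dnpep and 1.24 for Ihh. In Inv3 minus Inv1 the negative ones were -4.30 for Ptprn, -2.33 for Tuba4a, -1.66 for Resp18, -0.997 for Pax3, -0.73 for Dnajb2, -0.73 for Dnpep, -0.44 for Fam134a, -0.37 for Abcb6, -0.35 for Ttll4, -0.28 for Atic and -0.26 for Rqcd1. The positive ones of that pair were 6.19 for Fev, 1.64 for Ihh, 1.12 for Cdk5r2, 1.06 for Kcne4, 0.96 for Prkag3, 0.95 for Abca12 and 0.37 for Epha4. In Inv4 minus Inv1 they were -4.19 for Ptprn, -2.28 for Tuba4a, -0.82 for Dnajb2, -0.74 for Dnpep, -0.49 for Fam134a, -0.43 for Abcb6, 2.70 for Prkag3, 1.61 for Ihh, 1.41 for Cyp27a1 and 0.35 for Wdfy1. In Inv3 minus Inv2 they were 6.21 for Fev, 1.11 for Cdk5r2 and -0.68 for Tuba4a. In Inv4 minus Inv2 they were 2.36 for Prkag3, 1.79 for Cyp27a1 and -0.62 for Tuba4a, and in Inv4 minus Inv3 they were -6.17 for Fev, 1.74 for Prkag3 and 1.72 for Cyp27a1.

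Ihh rose and Pax3 fell in Inv2, Inv3 and Inv4, in comparisons that share the wild type libraries. For Ihh the shared libraries are argued against as the whole account, because they cancel in the difference from Inv1, where the smallest absolute z of the 3 was 3.29. For Pax3 the smallest was 1.48, with only Inv3 past the threshold, so chance in the wild type libraries may hold part of its fall in Inv2 and Inv4. A difference in embryo age or dissection also stays open, since Des, the only other gene of the muscle list in these tables, had a smallest z of 1.88 against wild type and is itself a gene of the locus, while Speg, also a gene of striated muscle, had log2 changes of -0.06, 0.09 and -0.02. At least 27.6% of all tested genes were called in Inv3 and at least 19.8% in Inv4, so a general difference between these libraries and wild type stays open as well. An effect of the inversions themselves is the biological explanation that the design names, and it was not tested apart from these.

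Genes raised in Inv1 were lower in Inv1DelCTCF than in Inv1, each by less than it had risen. Ptprn had log2 changes of 3.82 against wild type and -0.80 against Inv1, and Tuba4a 1.84 and -0.61. Inv1DelCTCF was not compared with wild type, so no return to the wild type level is shown. The 6 genes had a median log2 change of -0.47, where the middle 95% of matched lists ran from -0.19 to 0.17. After the GC trend was subtracted their median was -0.39, against -0.13 to 0.16. They thus fell farther than random genes of like mean count. The FGF list, which holds no locus gene, also lay below its matched lists, with a median of -0.42. The test therefore cannot tell an effect at the locus from a difference between the Inv1DelCTCF and Inv1 libraries that moves related genes together. Chance in the shared Inv1 libraries gave 3 or more called falls in 0% of 10000 simulations without a true change, against 3 observed. After the trend was subtracted 2 of the 6, Tuba4a and Ptprn, were called, and that step was not simulated. Loss of the CTCF site may lower these genes, as a hypothesis found and tested on the same data, and such a library difference stays open beside it.

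Many genes across the genome differed between Inv1DelCTCF and Inv1, and a candidate explanation is a GC bias between the 2 sets of libraries. With the trend in GC content and length subtracted, 395 genes were called, 31.0% of those before, under the third set in advance as the mark of such a cause. A straight line in GC content alone left 442, or 34.7%, which is just over that mark, so the test was close. The subtraction removes any change that follows GC content, whether it arose in the libraries or in the embryos. The number of calls left therefore cannot tell a bias between libraries from a true change of GC-rich genes. After the trend was subtracted the patterning list went from -0.16 to -0.08 and the gene-dense list from -0.13 to 0.01, and neither passed. The trend does not account for the median of the FGF list, which was then -0.37. Nor does it account for the cartilage and muscle medians, which went from 0.45 and 0.59 to 0.57 and 0.69. The test of a different share of ectoderm cells took the smaller of these, 0.57, which lay above its matched lists. Those lists understate the spread of the cartilage and muscle medians, so that test decides nothing. A different share of ectoderm cells stays open for these lists and for the other genes. The genes called higher, with no ectoderm marker among the 427, had a median 0.33 above that of all tested genes, but they were chosen for being higher and a GC trend alone puts genes on both sides, so this value decides nothing. A difference in embryo age cannot be told apart from the genotype, since let-7 and Lin28 pathway genes, which decline with age, had a median of -0.13 (permutation p = 0.152, two-sided), with Trim71 (-1.04) and Igf2bp1 left out because their values prompted the idea, and there are no values per library.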

How the results depend on the processing

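No paired analysis was possible because the tables hold no values per library, and leaving out a library, other splits of the samples and a check for duplicate libraries were not run for the same reason. Over 51 results, 167 values under alternatives kept their side of the threshold or stayed within 1.5 times the count. These include results that never passed and whose sign turned, such as the hedgehog list, from -0.13 to 0.01 after the GC trend was subtracted. Of the other values, 22 counts moved farther, 8 values no longer passed, 5 passed only under the alternative and 1 reversed. The subtraction of a trend or a line in GC content and the restriction of lists to genes with a deposited adjusted p were chosen after seeing the data. At an adjusted p under 0.01 Inv3 kept 16 called genes and Inv4 9, and the locus lists 13 in Inv3 and 3 in Inv1DelCTCF, while at 0.1 they held 17 in Inv4. With an absolute log2 change of at least 1 the counts were 3 in Inv1, 7 in Inv3 and 4 in Inv4, and with at least 0.5 they were 8 in Inv3 and 7 in Inv4. A Bonferroni limit over only the genes listed for each inversion, which is milder than one over the genome, left 14 and 8 in the same order. In Inv1DelCTCF 11.7% of the genes with an adjusted p were called, against 5.13% at an adjusted p under 0.01, 0.0357% and 1.55% with absolute log2 changes of at least 1 and 0.5, 1.03% under a Bonferroni limit, 3.52% after the trend was subtracted and 3.94% after the line. A minimum mean of 10 or 50 and the removal of the sex-linked list took away no called gene there, so these settings, which are counted among the 167, say nothing about its stability. Adjustment over the rows of the table gave 11 genes in Inv1, and over the locus list alone 12, because fewer genes are then tested. The median of the gene-dense list went from -0.13 to -0.10 with a mean of at least 10 and to -0.082 among genes with an adjusted p. It passed in neither setting (adjusted permutation p = 0.0923 and 0.189), and it reversed to 0.012 after the trend was subtracted. After that subtraction the patterning list no longer passed (-0.076), nor did the nerve list (0.35), which also failed at a mean of at least 10 (0.29) and among genes with an adjusted p (0.20), while the macrophage list then passed (0.38). The Wnt list failed among genes with an adjusted p (-0.15). By the median Wald score the hedgehog (-1.80), endothelium (-1.35) and macrophage (1.25) lists passed. With the shared wild type part removed, 17 genes differed between Inv4 and Inv1 and 10 between Inv3 and Inv2. On Wald scores the Pearson correlation of Inv1 and Inv2 passed its permutation test against 0 (0.288). It lay within the 0.191 to 0.595 of unchanged groups with shared controls, so it is no evidence of agreement beyond them. Nor does it show a lack of agreement, since the covariance of that pair on Wald scores, 1.68, lay above its simulated limit of 0.671. The Spearman correlation of Inv1 and Inv4 on Wald scores did not pass (0.150). Where no test or construction is named, the cause was not tested. Depth per library is unknown, and the shrunken fold changes limit what the wild type tables show for genes of low counts.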

Other observations

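The tests of gene order below were chosen after the raised genes were seen.

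The 6 genes raised in Inv1 lay close together, with a mean distance of 4.33 places in the order of the 78 listed genes, against 26.3 for random sets (permutation p = 0.00015, adjusted p = 0.00075). Random placement is therefore argued against for Inv1. The 13 genes raised in Inv3 had a mean distance of 23.5 (permutation p = 0.177) and the 10 raised in Inv4 one of 28.8 (permutation p = 0.887), so no clustering was detected among them. In Inv3 and Inv4 the rises may include changes unrelated to position, such as those of Igfbp5 and Abca12 at the far centromeric end of the listed genes.

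Wnt6 stood apart among genes with a mean of at least 300 in how its values compare between tables. Its rebuilt Inv1 level differed from the one implied by the Inv1DelCTCF table by a log2 residual of -0.69, the only one of 49 genes beyond 0.3. Some genes of lower mean had larger residuals, which before the median offset of -0.137 was taken off were -1.82 for Fev, -1.535 for Ihh and -1.18 for Prkag3. Others did not, such as Vil1 at 0.07 and Rufy4 at 0.13. Fev, Ihh and Prkag3 were each raised in at least 1 other inversion, and their Inv1 levels were rebuilt from shrunken fold changes. The mismatch may therefore lie in the rebuilt levels. Whether it lies there or in the values of Inv1DelCTCF was not tested, for Wnt6 as well.

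The Spearman correlation of the log2 change with GC content was 0.455 over 78 genes in Inv1 against wild type and -0.517 over 10945 genes in Inv1DelCTCF against Inv1. The Inv1 libraries enter these 2 comparisons with opposite sign, so a GC bias in them alone gives opposite correlations, and the opposition was not tested. Correlations with GC content against wild type were 0.160 in Inv2, 0.312 in Inv3 and 0.130 in Inv4. The genes listed against wild type lie in 1 region, so that GC content and position are mixed there.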
